A study of Mus musculus with 8 samples.

How the data were processed

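Liver RNA from 3 WT and 5 Abhd15 KO mice was measured on Affymetrix Mouse Gene 2.0 ST arrays, 1 array per sample. Groups and replicate numbers were taken from the sample titles. The labels describe each sample as coming from a mouse and the design text speaks of individual samples, but neither lists the animals, so p-values measure the spread between these samples. Per the labels' protocols, RNA was extracted with Trizol, and 200 ng of it was amplified and labelled with biotin.

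The authors deposited a table of expression values on the log2 scale, with 41345 transcript clusters and 8 arrays. Per the submitters' processing notes, RMA and the oligo package were used, and per the series design text the primary output went through Expression Console. Which of these made the deposited values, the versions, the RMA settings and any filter are not given in the sources used here. RMA as commonly run subtracts background, applies quantile normalization and summarises probes by median polish, which compresses the differences of dim clusters and shares information between arrays. That the scale is log2 was taken from the range of the values, 0.409 to 13.27, and could not be checked against scanner files, which were not used here. The deposited columns were used as they stand. The background correction could not be changed, and no slide, scan date, cage or harvest order was given, so no batch could be tested.

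Clusters were named through the platform's annotation table, in which 23521 rows have 1 gene symbol and 1814 have several, while 16010 rows are not listed and are unnamed here. Of the single-symbol clusters, 23328 matched an Entrez gene in NCBI RefSeq's table for the GRCm38.p6 assembly, which changed 0 symbols. They stand for 22180 genes, of which 1082 have several clusters. No gene was named from a cluster with several symbols. No coordinates are given, because the sources used here name no genome build for the values. The RefSeq table served only for names and for gene order.

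The comparison was KO minus WT over all 8 arrays with limma 3.58.1 in R 4.3.3 (input read with version 1.17.8 of the data.table package), using lmFit and eBayes without trend and without covariates, with 6 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the 23521 clusters with 1 symbol and a threshold of 0.05. Gene-level values are log2 means with the SD over arrays, and log2 differences with limma's standard error. Single values were also compared by an exact permutation test of the difference in means over the 56 splits of 8 arrays into 3 and 5. The number of arrays limits the precision of every value. Tested on simulated data with this design (23521 clusters, 10 runs, 50 changed clusters per size and run), the fit recovered 3.4% of log2 changes of 0.5, 59.8% of changes of 1, 95% of changes of 2 and 98.6% of changes of 3, and 4.39% of its calls were false. In the same way, a shift of 0.5 in a list of 20 genes was called in 10 of 10 runs, an unchanged list in 1 of 10, and a list with members shifted both ways in 0 of 10. Changes of all sizes were planted in the same runs, which eases the adjusted threshold. With few changed clusters, as in the real fit, the share recovered would be lower than these values. The simulated genes varied independently, and fewer lists were adjusted together than in the real data. In the real lists the estimated correlation between members reached 0.575 (acute phase), so the simulation does not give the rate of false list calls there.

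Gene lists for pathways and cell types were fixed before the data were examined, with 649 distinct genes, of which 582 were measured. They cover de novo lipogenesis, cholesterol synthesis and uptake, gluconeogenesis and fasting, fatty acid oxidation and ketogenesis, glycolysis and glycogen, insulin signalling, lipid droplets and lipolysis, the ABHD family, chromosomal neighbours of Abhd15, bile acids, xenobiotic metabolism, oxidative stress, the circadian clock, the unfolded protein and integrated stress response, immediate early genes, the acute phase, interferon response, male-biased and female-biased genes, oxidative phosphorylation, cell cycle and substrain differences. The marker lists cover hepatocytes, macrophages, stellate cells, sinusoidal endothelium, cholangiocytes, B cells, T and NK cells, neutrophils, erythroid cells, adipocytes, exocrine pancreas, skeletal muscle, and gallbladder and intestine. Some genes are in more than 1 list. Each gene was represented by its cluster with the highest mean. Lists with at least 5 measured members, 34 in all, were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, and adjusted over the 34 lists. Camera with an estimated correlation and fry, which tests a list on its own in 1 direction or in either, are given beside it. Adjusted p-values of lists are camera's with the preset correlation unless stated otherwise.

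Genes named in the text followed a rule fixed before the data were examined. Abhd15 came first. Up to 15 genes past the threshold per direction would be named, filled to 5 per direction by the smallest unadjusted p where fewer passed, leaving out predicted gene models. For each list up to 4 members that passed, or the 2 with the smallest unadjusted p, were named. Pde3b, Srebf1, Fasn, Pck1, G6pc, Irs2 and Igfbp1 were named whatever their values, and a further gene of this part of the rule is not reported here. Genes named outside the rule are marked as such where they appear.

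The alternatives fixed beforehand were centring each array on its median, repeating quantile normalization, cyclic loess, a minimum mean of 5, keeping the clusters above the median level, empirical Bayes with trend and robust settings, array weights, the replicate number as a block, leaving out each array in turn, testing every cluster, listed or not, keeping 1 cluster per gene, a minimum log2 difference of 0.5, averaging the clusters of a gene, an estimated correlation, and fry. Leaving out KO arrays 1 and 2 together was added after the data were seen, because they stood apart on the first principal component.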

Results

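Gene expression was measured in the liver of 8 male mice on the C57BL/6J background, 3 wild-type (WT) and 5 carrying a knockout (KO) of Abhd15. Abhd15 encodes an alpha/beta hydrolase domain protein known mainly from fat cells, where it has been studied with the phosphodiesterase Pde3b and the control of fat breakdown by insulin. The mice ate normal chow and were 14 weeks old according to the design text, although the sample labels give up to 14 weeks as the time on the diet. They had their livers taken after an overnight fast followed by 1 hour of refeeding, so the comparison addresses how loss of Abhd15 affects liver transcripts shortly after a meal. Each liver was hybridised to 1 Mouse Gene 2.0 ST array, which gives 1 log2 expression value for each transcript cluster, the array's unit for a gene. The array medians lay between 2.99 and 3.05 over 41345 clusters, and the correlation across clusters between any pair of arrays lay between 0.978 and 0.985, with clusters not being independent replicates. KO arrays 1 and 2 stood apart from the other arrays on the first principal component, which held 22.1% of the variance, with scores of 35.7 and 32.1 against 0.661 for the next array. KO array 4 stood apart on the second component (15.8% of the variance), at 41.8 against 4.16 for the next. KO array 5 lay lowest on the third (13.8%), at -32.4 against -14.8 for the next.

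Abhd15 itself was lower in the KO livers, with a log2 value of 5.64 ± 0.176 (SD, n = 3) in WT and 5.12 ± 0.0775 (SD, n = 5) in KO. The WT arrays read 5.647, 5.812 and 5.460, and the KO arrays 5.137, 5.042, 5.206, 5.175 and 5.035, so that each KO array lay below each WT array. The log2 difference of -0.52 (SE 0.129), or 1.44-fold, gave a two-sided exact permutation p of 0.0179, the smallest that the 56 splits of 8 arrays can give. Its adjusted p among all genes was 0.795 with limma. Leaving out KO arrays 1 and 2 gave a log2 difference of -0.50 with an exact p of 0.1, the smallest possible there. Another cluster for Abhd15 was dim, with a mean of 3.42 over all arrays and a log2 difference of -0.68 (SE 0.323, adjusted p = 0.838). Where the probes of either cluster lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal in KO livers checks the labels by its direction and not by its size. Of 14 measured members of the fixed list of Abhd15's chromosomal neighbours, 8 were higher and 6 lower, with a mean log2 difference of -0.01 while the median was 0.01 and the camera test pointed higher (adjusted p = 0.96). Slc6a4, the serotonin transporter, had a log2 difference of -0.40 (SE 0.157) at a dim level of 2.34, and -0.23 without WT array 1, and Blmh, bleomycin hydrolase, one of 0.15 (SE 0.127), and 0.09 without WT array 2.

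Across the 23521 clusters with a single gene symbol, which stand for 22180 genes, limma found 0 past an adjusted p of 0.05, and the smallest adjusted p was 0.154. At an unadjusted p under 0.05 there were 1429 clusters, 648 higher and 781 lower in KO, where chance gives 1176. In 1042 clusters (4.43%) the KO and WT arrays did not overlap, against 3.57% by chance. The smallest p belonged to Hspa1a, an inducible HSP70 chaperone of the heat shock response, with a log2 value of 6.31 ± 0.364 (SD, n = 3) in WT and 8.01 ± 0.286 (SD, n = 5) in KO. Its log2 difference was 1.70 (SE 0.206), or 3.25-fold, and all 5 KO arrays lay above all WT arrays. The neighbouring HSP70 gene Hspa1b read 8.94 ± 0.254 (SD, n = 3) in WT and 9.94 ± 0.224 (SD, n = 5) in KO, a log2 difference of 1.01 (SE 0.17) with an adjusted p of 0.349. The coding sequences of the pair are nearly identical, so their probes may not separate them. Hspa1a passed the threshold when only the 7699 clusters with a mean of at least 5 were tested (adjusted p = 0.0458), and both passed under empirical Bayes with trend and robust settings (adjusted p = 0.00543 and 0.0342). Over all settings the adjusted p of Hspa1a ranged from 0.00543 to 0.575.

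The other genes with the smallest p among those higher in KO were Cyp3a59, a cytochrome P450, with a log2 difference of 0.93 (SE 0.212), Parpbp with 0.61 (SE 0.125), and Aacs, the cytosolic acetoacetyl-CoA synthetase, with 0.51 (SE 0.117). Parpbp was dim, with a mean of 1.95. Among genes lower in KO, Acot3, a peroxisomal acyl-CoA thioesterase, read 7.11 ± 0.579 (SD, n = 3) in WT and 5.61 ± 0.322 (SD, n = 5) in KO, a log2 difference of -1.50 (SE 0.259, adjusted p = 0.376). Caln1, Krt14, Bbof1 and Wfdc1 had log2 differences of -0.89 (SE 0.135), -0.78 (SE 0.122), -1.05 (SE 0.166) and -0.70 (SE 0.133), all at mean levels of 4.01 or below, where a signal above background is not shown. In each of these genes except Cyp3a59, the KO and WT arrays did not overlap, and none passed the adjusted threshold.

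When every one of the 41345 clusters was fitted together, 3 passed, 1 higher and 2 lower, and all 3 were unnamed in the annotation used. Cluster 17550474 read 7.15 ± 0.538 (SD, n = 3) in WT and 2.61 ± 0.66 (SD, n = 5) in KO (adjusted p = 0.0202). Cluster 17267418 read 6.55 ± 0.248 (SD, n = 3) in WT and 3.08 ± 0.398 (SD, n = 5) in KO (adjusted p = 0.00619). Cluster 17205867 read 4.08 ± 0.208 (SD, n = 3) in WT and 5.74 ± 0.194 (SD, n = 5) in KO, 3.17-fold higher (log2 difference 1.67, SE 0.16, adjusted p = 0.0367). The KO values of the 2 lower clusters lay near or below the array medians of 2.99 to 3.05 and are not shown to be above background, so the size of their fall is not given. Each of the 3 gave an exact permutation p of 0.0179, with no overlap between the groups. The count of 3 became 0 without WT array 1, 0 without WT array 3, 0 without KO arrays 1 and 2, 2 without KO array 4, and 1 without any other single array. The log2 difference of cluster 17205867 stayed between 1.553 and 1.758.

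**Figure D1:**
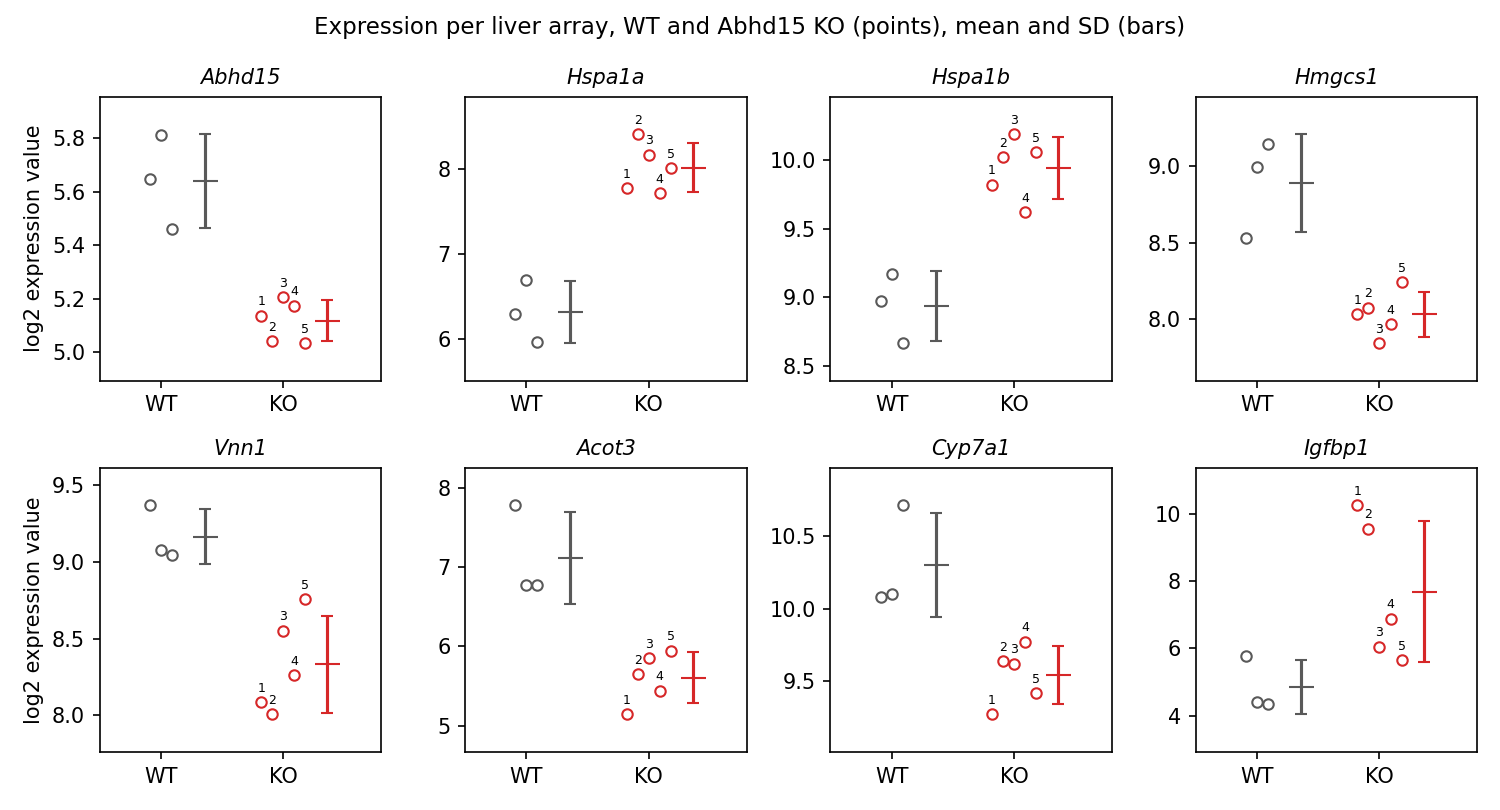
Log2 expression values of 8 genes (vertical axes, each with its own range) in 3 WT arrays (grey) and 5 Abhd15 KO arrays (red, numbered), with the mean and SD as bars beside the points. Abhd15, Hmgcs1, Vnn1, Acot3 and Cyp7a1 have all 5 KO points below the WT points and Hspa1a and Hspa1b have them above, while Igfbp1 is highest in KO arrays 1 and 2 (10.257 and 9.562).

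Genes of cholesterol synthesis and uptake fell as a group in KO liver. Of 19 measured members, 18 were lower and 1 higher, with a mean log2 difference of -0.46 (camera adjusted p = 8.41e-11, and adjusted p = 0.32 with an estimated correlation). The mean of the list was 6.839, 6.886, 6.840, 6.709 and 6.865 in the 5 KO arrays, below the 6.937, 7.457 and 7.475 of the WT arrays (exact permutation p = 0.0179). Hmgcs1, the cytosolic HMG-CoA synthase, read 8.89 ± 0.322 (SD, n = 3) in WT and 8.03 ± 0.147 (SD, n = 5) in KO, a log2 difference of -0.86 (SE 0.165). Cyp51, the lanosterol demethylase, had a log2 difference of -0.69 (SE 0.179). No member passed over all genes, and 6 passed when adjusted over the list alone. Besides these 2 they were Stard4, a sterol carrier (-0.88, SE 0.246), Sqle, squalene epoxidase (-0.85, SE 0.247), Mvk, mevalonate kinase (-0.69, SE 0.224), and Fdps, farnesyl diphosphate synthase (-0.49, SE 0.154), which were chosen after their values were seen. Without KO arrays 1 and 2 the mean log2 difference was -0.48 (camera adjusted p = 7.04e-09).

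Genes of fatty acid oxidation and ketogenesis fell as well, with 19 of 23 measured members lower and 4 higher. The mean log2 difference was -0.31 (camera adjusted p = 3.96e-08, and adjusted p = 0.305 with an estimated correlation), and all 5 KO arrays, at 8.771 to 8.954, lay below the WT arrays, at 9.025 to 9.306 (exact permutation p = 0.0179). Vnn1, a pantetheinase and known PPARA target, read 9.16 ± 0.179 (SD, n = 3) in WT and 8.33 ± 0.317 (SD, n = 5) in KO, a log2 difference of -0.83 (SE 0.189). Acaa1b, a peroxisomal thiolase, had a log2 difference of -0.79 (SE 0.192). No member passed over all genes, and 6 passed when adjusted over the list alone. The other 4 were the thioesterase Acot1 (-1.20, SE 0.335), the fatty acid binding protein Fabp1 (-0.63, SE 0.158), the peroxisomal enzyme Ehhadh (-0.60, SE 0.177) and the fatty acid hydroxylase Cyp4a14 (-0.44, SE 0.142), again chosen after their values were seen. Cpt1a, the entry step of mitochondrial oxidation, and Ppara, named after the values were seen too, had log2 differences of 0.04 (SE 0.126) and 0.06 (SE 0.164). Without KO arrays 1 and 2 the mean log2 difference was -0.29 (camera adjusted p = 1.61e-06).

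The lipid droplet and lipolysis list passed camera's test as lower, with 16 of 21 measured members lower and a mean log2 difference of -0.16 (camera adjusted p = 0.0222, and adjusted p = 0.702 with an estimated correlation). Its array means overlapped between the groups, from 7.413 to 7.87 in KO and from 7.612 to 7.866 in WT. The exact permutation p was 0.232, and KO array 5 had the highest mean of all arrays. Fitm1, which promotes lipid droplet formation, had a log2 difference of -0.49 (SE 0.164, and -0.29 without WT array 3), and Mgll, monoacylglycerol lipase, one of -0.50 (SE 0.191). No member passed, over all genes or when adjusted over the list alone. The call ended without KO arrays 1 and 2 (mean log2 difference -0.06, adjusted p = 0.379) and in 5 single omissions, without WT array 1 (mean -0.09, adjusted p = 0.34), WT array 2 (-0.17, 0.0577), KO array 1 (-0.12, 0.124), KO array 2 (-0.13, 0.0596) or KO array 3 (-0.16, 0.068). It also ended among clusters above the median level (mean -0.16, adjusted p = 0.117).

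The de novo lipogenesis list did not pass. Of 23 measured members, 10 were higher and 13 lower, with a mean log2 difference of 0.01 while the median was -0.04 and the camera test pointed lower (adjusted p = 0.96). Fasn, the fatty acid synthase, read 8.25 ± 0.0994 (SD, n = 3) in WT and 8.31 ± 0.626 (SD, n = 5) in KO, a log2 difference of 0.07 (SE 0.305). KO array 5 alone read 9.275, and the difference of Fasn was -0.18 without it, -0.01 without KO array 4 and 0.19 without KO array 1. Srebf1, which encodes the lipogenic factor SREBP-1, had a log2 difference of -0.27 (SE 0.294), which was 0.03 without WT array 2 and -0.72 without WT array 1. Pnpla3 and Dgat2, both of triglyceride metabolism, had differences of 0.40 (SE 0.191, and 0.21 without WT array 1) and 0.21 (SE 0.124).

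Among bile acid genes, 9 of 20 were higher and 11 lower, and the list as a whole did not pass (mean log2 difference -0.07, camera adjusted p = 0.543). It passed fry's mixed test, which asks whether members change in either direction (adjusted p = 0.00103). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 10.3 ± 0.36 (SD, n = 3) in WT and 9.54 ± 0.199 (SD, n = 5) in KO, a log2 difference of -0.76 (SE 0.183), and was the 1 member past the threshold when adjusted over the list alone. Slco1a4, an organic anion transporter, had a log2 difference of 0.43 (SE 0.136). The fatty acid oxidation list also passed the mixed test (adjusted p = 0.0148), and no list passed fry's directional test, where the smallest adjusted p was 0.109.

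Immediate early genes, which respond within minutes to stimuli, rose as a group, and the rise was carried by 2 livers. All 24 measured members were higher in the KO mean, with a mean log2 difference of 0.65 (camera adjusted p = 2.7e-09, and adjusted p = 0.616 with an estimated correlation). The list mean was 6.721 and 6.842 in KO arrays 1 and 2, against 5.612, 5.388 and 5.504 in the other KO arrays and 5.357, 5.445 and 5.291 in WT (exact permutation p = 0.143). Without KO arrays 1 and 2 the mean log2 difference was 0.14 and the list no longer passed (camera adjusted p = 0.0618). Atf3, a stress-induced transcription factor, had a log2 difference of 0.85 (SE 0.32), and Klf4 one of 0.45 (SE 0.168). No member passed, over all genes or when adjusted over the list alone.

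The gluconeogenesis and fasting list rose with the same 2 arrays. Of 19 measured members, 17 were higher, with a mean log2 difference of 0.48 (camera adjusted p = 7.96e-05, and adjusted p = 0.702 with an estimated correlation). The list mean was 8.770 and 8.625 in KO arrays 1 and 2, against 7.809, 7.913 and 7.833 in the other KO arrays and 7.804, 7.750 and 7.585 in WT (exact permutation p = 0.125). Igfbp1, a secreted protein repressed by insulin, read 10.257, 9.562, 6.051, 6.884 and 5.656 in the KO arrays and 5.781, 4.409 and 4.353 in WT, a log2 difference of 2.83 (SE 0.985). Slc25a25, a mitochondrial carrier, had a log2 difference of 0.89 (SE 0.263), G6pc, the catalytic unit of glucose-6-phosphatase, 0.67 (SE 0.374, and 0.41 without KO array 2), Irs2 0.53 (SE 0.466, with 0.25 without KO array 1 and 0.84 without WT array 3) and Pck1 0.06 (SE 0.244). The sign for Pck1 turned without WT array 3 (-0.06), KO array 1 (-0.05) or KO array 2 (-0.04), and its difference was 0.23 without KO array 5. No member passed, over all genes or when adjusted over the list alone. Without KO arrays 1 and 2 the mean log2 difference was 0.14 (camera adjusted p = 0.247). The differences of Igfbp1, Slc25a25, G6pc, Irs2 and Pck1 were then 1.35, 0.57, 0.11, -0.14 and -0.22.

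The acute phase list, of inflammation-induced liver proteins, rose as a group, with 22 of 24 members higher and a mean log2 difference of 0.28 (camera adjusted p = 0.00115, and adjusted p = 0.86 with an estimated correlation). Its array means overlapped between the groups, from 8.888 to 10.02 in KO and from 8.951 to 9.385 in WT, and the exact permutation p was 0.339. Mt2, a metallothionein, had a log2 difference of 0.85 (SE 0.244), and Serpina3n one of 0.46 (SE 0.183). No member passed, over all genes or when adjusted over the list alone. The call ended without KO arrays 1 and 2 (mean log2 difference 0.11, adjusted p = 0.379), without KO array 1 alone (0.12, adjusted p = 0.124) and without WT array 2 (0.18, adjusted p = 0.0577).

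The unfolded protein and integrated stress list rose as a group, with 18 of 22 members higher and a mean log2 difference of 0.21 (camera adjusted p = 0.0113, and adjusted p = 0.616 with an estimated correlation). All 5 KO arrays, at 7.378 to 7.491, lay above the WT arrays, at 7.09 to 7.368 (exact permutation p = 0.0179). Asns, asparagine synthetase, read 7.749, 7.511, 5.290, 5.527 and 5.262 in the KO arrays and 4.915, 4.348 and 4.790 in WT, a log2 difference of 1.58 (SE 0.582). Without KO arrays 1 and 2 the list's mean log2 difference was 0.23 (camera adjusted p = 6.96e-05), and without WT array 1 it was 0.14 and did not pass (adjusted p = 0.439). The circadian clock list rose as a group, with 16 of 19 members higher and a mean log2 difference of 0.18 (camera adjusted p = 0.0089, adjusted p = 0.305 with an estimated correlation, exact permutation p = 0.0357). Per1 had a log2 difference of 0.65 (SE 0.201) and Bhlhe40 one of 0.44 (SE 0.155), both parts of the clock's negative arm. Without KO arrays 1 and 2 the clock list did not pass (mean log2 difference 0.14, adjusted p = 0.169). No member of either list passed, over all genes or when adjusted over the list alone.

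**Figure D2:**
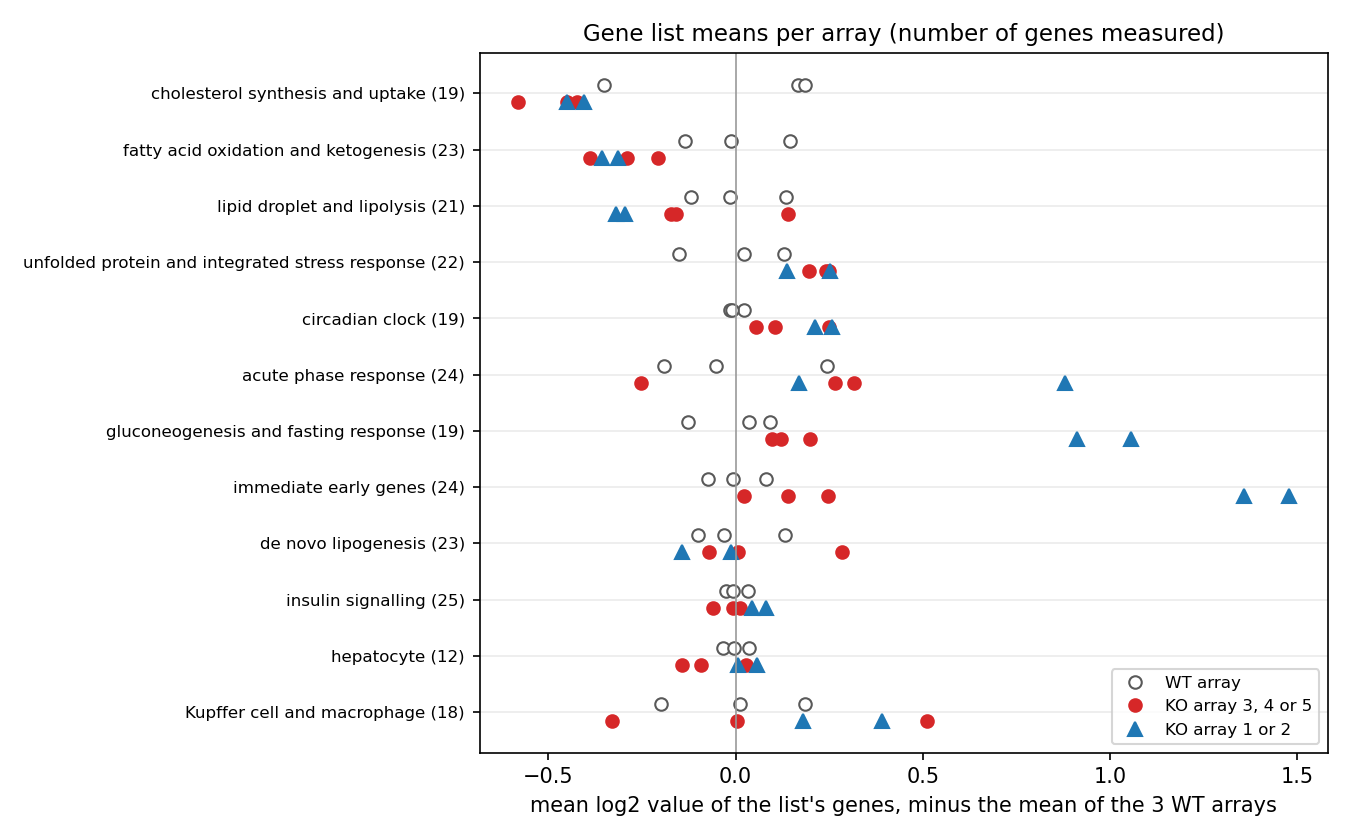
Mean log2 value of the measured genes of 12 lists in each array, minus the mean of the 3 WT arrays (horizontal axis), for WT arrays (open circles), KO arrays 3, 4 and 5 (red circles) and KO arrays 1 and 2 (blue triangles), with the number of genes in parentheses. The cholesterol and fatty acid oxidation lists place all 5 KO arrays below the WT arrays, and the immediate early and fasting lists place KO arrays 1 and 2 above every other array.

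In all, 8 of 34 tested lists passed with camera's preset correlation, 5 higher and 3 lower, and 0 passed with an estimated one, where 3 had an unadjusted p under 0.05. No list passed the exact permutation test of its mean after adjustment over the lists, where the smallest adjusted p was 0.208. With 56 splits at least 13 of the 35 lists, the erythroid one included, would have to reach the smallest possible p of 0.0179 for any to pass, and 3 did, so this adjustment could hardly have given a call. The remaining pathway lists did not pass. The insulin signalling list had 11 of 25 members higher, with a mean log2 difference of 0.01 against a median of -0.02 (adjusted p = 0.96). Foxo1 and Pik3cb had log2 differences of 0.27 (SE 0.137) and -0.28 (SE 0.16). Pde3b, the partner of Abhd15 in fat cells, read 8.80 ± 0.0335 (SD, n = 3) in WT and 8.78 ± 0.112 (SD, n = 5) in KO, a log2 difference of -0.02 (SE 0.122), whose sign turned in 3 of 19 settings, cyclic loess and the omission of KO array 3 among them, and which was -0.07 without KO array 2. The glycolysis and glycogen list had 8 of 20 higher (mean -0.05, adjusted p = 0.654), with Ppp1r3b and Ppp1r3g, regulators of glycogen synthesis, at -0.25 (SE 0.127, and -0.16 without WT array 2) and -0.28 (SE 0.149). The ABHD family list, with 8 of 17 higher, had a mean of -0.05 (adjusted p = 0.654). Its members Abhd6 and Abhd18 had log2 differences of -0.50 (SE 0.242, and -0.21 without KO arrays 1 and 2) and -0.25 (SE 0.177). The xenobiotic list had 12 of 19 higher (mean 0.07, adjusted p = 0.566), with Sult1d1 at 0.59 (SE 0.21) and Cyp2c55 at 0.82 (SE 0.294). The oxidative stress list had 7 of 16 higher (mean -0.03, adjusted p = 0.654), with Hmox1, heme oxygenase 1, at 0.90 (SE 0.347) and Gstm4 at -0.50 (SE 0.221). Without KO arrays 1 and 2 the difference of Hmox1 was 0.41.

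The interferon list had 13 of 21 members lower, with a mean log2 difference of -0.09 (adjusted p = 0.207), and it passed without KO arrays 1 and 2 (mean -0.28, adjusted p = 0.00122), without WT array 1 (-0.21, 0.0146) and without KO array 1 (-0.19, 0.0169). Its direction turned without WT array 3 (mean 0.07, adjusted p = 0.905), and its mean was -0.00412 without KO array 4 (adjusted p = 0.584). Ddx58, the RNA sensor RIG-I, had a log2 difference of -0.46 (SE 0.14), and Usp18 one of -0.72 (SE 0.257). The male-biased list had 10 of 22 higher (mean -0.01, adjusted p = 0.936), with Cyp7b1 at 0.48 (SE 0.214) and Ugt2b38 at 1.43 (SE 0.65), which was 0.58 without WT array 2. The female-biased list had 9 of 17 higher, with a mean of -0.12 against a median of 0.06 (adjusted p = 0.566). Its member Acot3 passed when adjusted over the list alone, and Cyp2c40 had a log2 difference of -1.31 (SE 0.458). Oxidative phosphorylation genes were lower in 19 of 26 members (mean -0.05, adjusted p = 0.384), with Cycs at -0.23 (SE 0.154) and Ndufs1 at -0.16 (SE 0.123). The cell cycle list had 11 of 22 higher (mean 0.05, adjusted p = 0.654), with Mki67 at 0.53 (SE 0.172) and Birc5 at -0.31 (SE 0.136), both dim. Genes known to differ between C57BL/6J and C57BL/6N substrains had a mean of -0.00209 against a median of 0.03 over 5 members (adjusted p = 0.936), with Nnt at -0.14 (SE 0.123, and -0.09 without WT array 1) and Ide at -0.15 (SE 0.175), the latter 0.05 without WT array 2 and -0.29 without WT array 1.

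None of the cell type marker lists passed. Hepatocyte markers had 4 of 12 members higher, with a mean log2 difference of -0.03 (adjusted p = 0.936), with Hal at 0.33 (SE 0.151) and Glul at -0.30 (SE 0.165). Kupffer cell and macrophage markers had 10 of 18 higher (mean 0.15, adjusted p = 0.294), with Cd14 at 0.75 (SE 0.238) and Mpeg1 at 0.57 (SE 0.32, and 0.37 without WT array 1 and 0.90 without WT array 3), and the list passed without WT array 3 (mean 0.24, adjusted p = 0.0204) and without KO array 4 (0.27, 0.00455). Its mean was 0.05 without WT array 2 (adjusted p = 0.995), 0.06 without KO array 3 (0.86), 0.09 without KO array 1 (0.598) and 0.06 without KO arrays 1 and 2 (0.592). Stellate cell and fibrosis markers had 11 of 17 higher (mean 0.06, adjusted p = 0.566), with Tgfb1 at 0.41 (SE 0.133) and Lrat at -0.34 (SE 0.136). Sinusoidal endothelial markers had 5 of 14 higher (mean -0.02, adjusted p = 0.916), with Ehd3 at -0.31 (SE 0.171) and Lyve1, a hyaluronan receptor, at 0.65 (SE 0.164). Lyve1 was above all WT arrays in 5 of 5 KO arrays and passed when adjusted over the list alone. Cholangiocyte markers had 4 of 10 higher, with a mean of -0.00905 while the camera test pointed higher (adjusted p = 0.96), with Epcam at -0.42 (SE 0.193) and Krt19 at 0.26 (SE 0.143, and 0.15 without WT array 1).

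Markers of blood cells and of tissues that could be taken along were mostly dim. B cell markers had a mean log2 difference of 0.07 over 9 members (adjusted p = 0.543), with Blk at 0.47 (SE 0.176, and 0.31 without WT array 2) and Fcrla at 0.25 (SE 0.143). T and NK cell markers had one of 0.08 over 14 (adjusted p = 0.43), with Cd8b1 at 0.32 (SE 0.158) and Ccl5 at 0.52 (SE 0.292, and 0.31 without KO array 3). Neutrophil markers had one of 0.10 over 13 (adjusted p = 0.384), with Csf3r at 0.35 (SE 0.206, with 0.08 without WT array 1 and 0.56 without WT array 3) and Camp at 0.27 (SE 0.169, and 0.16 without KO array 3). Only 4 erythroid markers were measured, too few for the test, with a mean of 0.14, Slc4a1 at 0.26 (SE 0.158, and 0.10 without WT array 2) and Epb42 at 0.20 (SE 0.129). Adipocyte markers had a mean of 0.02 over 9 members, while the median was -0.00307 and the test pointed lower (adjusted p = 0.96), with Fabp4 at 0.73 (SE 0.351, and 0.17 without WT array 3) and Adipoq at -0.47 (SE 0.336, with -0.13 without WT array 1 and -0.85 without WT array 2). Exocrine pancreas markers had a mean of 0.02 over 14 members against a median of -0.01 (adjusted p = 0.915), with Prss3 at 0.68 (SE 0.422, and 0.42 without KO array 5) and Ctrb1 at -0.29 (SE 0.189). Skeletal muscle markers had a mean of 0.04 over 13 (adjusted p = 0.654), with Ckm at -0.54 (SE 0.178) and Actn3 at 0.33 (SE 0.146). Gallbladder and intestinal markers had a mean of -0.10 over 11 (adjusted p = 0.384), with Vil1 at -0.33 (SE 0.173, and -0.19 without WT array 2) and Fabp2, which was bright in these livers at a mean of 9.15, at -0.42 (SE 0.175).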

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

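Of the tests in this part, those of the immediate early genes, of food intake, of hepatocyte share and of the splits for the whole table were chosen only after the results were seen. Those of the heat shock genes and of the other splits were written down before their values were seen.

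Over 123 groups of 5 KO values, covering the named genes, the lists and the 3 unnamed clusters, 4 had an array far from the rest. Chance gives about 1 in 20, so these 4 are no more than chance would give. The groups also overlap, as the lists hold named genes. Usp18, an interferon-induced protease, read 4.605 in KO array 4 with 5.512 as the nearest KO value. Lyve1 read 8.21 in KO array 1 against 7.651 for the nearest, and Pde3b 8.976 in KO array 2 against 8.758. The mean of the cholesterol synthesis and uptake list was 6.709 in KO array 4 against 6.839 for the nearest. Among clusters left out of the main comparison because the annotation does not name them, cluster 17205867 was higher in KO, at 5.74 against 4.08 in WT.

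The number of genes past the threshold in the real grouping was 0, and the highest of the other splits of the 8 arrays gave 2. Any split gives at least 0, so that all 56 gave as many says nothing about chance. For the 1429 clusters with an unadjusted p under 0.05, 8 of 56 splits gave as many and the highest other gave 1936, so chance cannot be excluded for that count. The highest split set KO arrays 1, 2 and 3 against the rest. For the 8 lists past the threshold, 3 of 56 splits gave as many and the highest other gave 12, and chance cannot be excluded. For the 3 clusters of the whole table, 1 of 56 splits gave as many, the real one, which is the smallest share that 56 splits can give, and the highest other gave 1. That share is under 0.05, which makes chance less likely for that count but does not exclude it. The test was chosen after the 3 clusters were seen, and leaving out WT array 1, WT array 3 or KO arrays 1 and 2 brings the count to 0.

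The immediate early genes were high in KO arrays 1 and 2. More immune cells in these 2 livers stay open, since 54 markers of macrophages, neutrophils, B cells and T and NK cells together differed from the other 3 KO arrays by 0.103 (SE 0.112), with macrophage markers at 0.224 (SE 0.267), neutrophil markers at 0.144 (SE 0.18) and the dim T and NK cell markers at -0.0876 (SE 0.0271). Handling at harvest cannot be told apart from a real difference in these mice: the 18 fasting genes outside the immediate early list were also higher in the 2 arrays, by 0.739 (SE 0.0861), and neither harvest order nor food intake is recorded in the sources used here. An effect of genotype stays open and was not tested, as the arrays were singled out for standing high.

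Hspa1a and Hspa1b were higher in all 5 KO arrays than in all WT arrays. A general heat shock response was tested on 16 other measured heat shock genes, of which 14 were higher. Their median log2 difference was 0.162, between the bounds of 0.1 and 0.2 set beforehand, so it stays open (camera p = 9.41e-07, p = 0.0349 with an estimated correlation, exact permutation p = 0.0357). An effect of genotype stays open, and a shared difference in housing or handling between the groups, which no label gives, was not tested.

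The fatty acid oxidation and cholesterol lists were lower in KO. Less food eaten by KO mice in the refeeding hour stays open for the oxidation list. The fasting list was higher by 0.477 (SE 0.219), which goes with it, but by 0.1388 without KO arrays 1 and 2 (camera adjusted p = 0.247). The oxidation list, which fasting raises, was lower in all 5 KO arrays, which goes against less food. That list stayed at -0.2948 without KO arrays 1 and 2 (camera adjusted p = 1.61e-06). Of 20 other PPARA targets, 18 were lower too, but many are enzymes of the same pathway and so are not separate evidence. For the cholesterol list, less food was predicted to lower the de novo lipogenesis list too, which differed by 0.0132 (SE 0.0998). That goes against less food only if this list responds within 1 hour of refeeding, which these data do not show. Its member Srebf1 was at -0.27 (SE 0.294), at -0.72 without WT array 1 and at 0.03 without WT array 2. Less food stays open there, also because the fasting list was higher, a rise that fell to 0.1388 without KO arrays 1 and 2. The cholesterol list was lower in all 5 KO arrays and stayed at -0.4848 without those 2 (camera adjusted p = 7.04e-09). A lower share of hepatocytes is argued against for both, since the lists differed from the hepatocyte markers, themselves at -0.0288, by -0.282 (SE 0.106) and -0.433 (SE 0.161). An effect of genotype stays open for both lists, as does any difference between the groups that the labels do not record.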

How the results depend on the processing

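Leaving out KO arrays 1 and 2 was chosen after the data were seen, and the other settings were fixed beforehand. The count of 0 genes (limma, 1429 at an unadjusted p under 0.05) became 1 with a minimum mean of 5 (Hspa1a, adjusted p = 0.0458), 3 with trend and robust settings (Hspa1a, Hspa1b and the gene model 1700080G11Rik, named after its value was seen, at -1.562, adjusted p = 0.0342), and 3 with every cluster of the table (the unnamed ones), and it stayed at 0 in the other settings except the block below, with 1177 to 1699 clusters at an unadjusted p under 0.05 when single arrays were left out. The cause was not tested for the minimum mean, which changes both the number of clusters and the variance prior, or for trend and robust settings. The log2 difference of Abhd15 stayed between -0.6105 and -0.4345 when single arrays were left out, and was -0.501 without KO arrays 1 and 2, where the 3 remaining KO arrays allow no p below 0.1. The count of 8 lists became 0 with an estimated correlation, 0 with fry, and 4 without KO arrays 1 and 2 (1 higher and 3 lower, the interferon list among them), and lay between 6 and 9 when single arrays were left out. The estimated correlation between members was 0.334 in the cholesterol list and 0.117 in the oxidation list. It was 0.42 in the fasting, 0.496 in the immediate early and 0.575 in the acute phase list. The preset 0.01 understates these, which makes camera's preset p-values too small there. The clock list also lost its call at 0.00735, below the preset, so correlation alone does not account for every lost call. The cause was not tested for fry. Of 19 settings, the cholesterol and fatty acid oxidation lists kept their calls in 17, the fasting, clock and immediate early lists in 16, the stress list in 15, the acute phase list in 14 and the lipid droplet list in 10. The macrophage list, which did not pass, passed among clusters above the median level (adjusted p = 0.0205), where the lipid droplet list did not (adjusted p = 0.117). Among single values of named genes, 13 changed sign, all without a call, and 1529 kept direction and side of the threshold. Of 84 named genes, 25 had a difference that moved by over 1.5 times when a single array was left out. Genes near the array background are limited by their dim signal: only 7699 of 23521 clusters had a mean of at least 5.

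With the replicate number as a block (replicate block), 1 gene passed, Moxd1, also named after its value was seen, at 5.65 (adjusted p = 0.00112), 8 lists passed, with the macrophage list (adjusted p = 1.7e-05) in place of the stress list (adjusted p = 0.21), the interferon list turned to 0.0843, Fasn to -0.3567 and Pde3b to 0.00133, none of which passed, and Abhd15 was at -0.51. Moxd1 read 8.149, 8.052 and 7.977 in KO arrays 1, 2 and 3 but 3.017 and 2.025 in KO arrays 4 and 5, which the block leaves out of the contrast. Arrays with the same number did not deviate together (r = -0.048, 0.016 and 0.021 across clusters), so the numbers do not pair WT with KO arrays. Whether they follow an order or batch within the KO group was not tested. The split of KO arrays 1, 2 and 3 against the rest gave 1936 clusters with an unadjusted p under 0.05 (limma), the most of all splits.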

Other observations

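The lists of this part were written after the main results were seen but before their own values were, and the 3 genes named from each of the first 2 lists were chosen after their values were seen, by the smallest p. Other targets of PPARA, the nuclear receptor that drives fatty acid oxidation in the fasted liver, were lower in KO in 18 of 20 measured genes, all outside the fixed lists. Slc22a5, the carnitine transporter, had a log2 difference of -0.609 (SE 0.225), Acot4, a peroxisomal thioesterase, one of -0.559 (SE 0.184), and Retsat, retinol saturase, one of -0.312 (SE 0.117). Among the other heat shock genes, Serpinh1, a collagen chaperone, had a log2 difference of 0.611 (SE 0.167), Hspb8 one of 0.485 (SE 0.149) and Hsph1 one of 0.444 (SE 0.145). None of these genes passed the threshold over all genes (adjusted p = 0.795 for each).

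A hypothesis is that PPARA activity was lower in KO livers at this time point. It needs the other targets to be lower too, and their median log2 difference was -0.196 (camera p = 1.1e-06, p = 0.0413 with an estimated correlation, exact permutation p = 0.0179), where a median above -0.05 would have spoken against it. Leaving out single arrays kept the median between -0.217 and -0.157, with camera p at most 0.000572. Other well-known PPARA targets, which stand in the fixed lists and are named here after their values were seen, were not lower beyond their error: Cd36 had a log2 difference of 0.296 (SE 0.194), Pdk4 0.1933 (SE 0.405), Angptl4 0.1519 (SE 0.264), Cpt1a 0.0442 (SE 0.126) and Fgf21 -0.06033 (SE 0.344). The median of the other targets goes with the hypothesis, but these 5 genes do not add to it. Many of the other targets, such as Hadh, Acads, Ech1 and Eci2, are themselves enzymes of fatty acid oxidation. Any cause that lowered the oxidation list could lower them too, so the test does not single out PPARA. The targets also respond to feeding, food intake stays open, and protein activity was not measured. A further hypothesis was that a higher sterol level lowered the cholesterol list and would then also raise LXR targets. Of 12 LXR targets, 6 were higher and 6 lower, with a median of 0.0015, while the mean was -0.0783 (exact permutation p = 0.0357, camera p = 0.379). The median lies under the bound of 0.05 set beforehand, below which the values were to speak against the hypothesis, and the set showed no rise. As the members go both ways, and 4 of them are in other lists, this evidence against it is weak, and sterol levels were not measured.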
